A study of Rattus norvegicus with 9 samples.

How the data were processed

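Whole lung of 9 male Wistar rats was profiled, with 3 arrays for each of CS, PM2.5 and control, called biological replicates in the labels. The age given is 6 to 8 weeks, which is shorter than the 90 days of exposure and so cannot be the age at sampling. Per the labels, frozen lung was ground, RNA was taken up in TRIzol and labelled with the Agilent Quick Amp kit, and 1 array was run per sample. The deposited scanner files give intensity on a linear scale, from a 1-colour scan read with Agilent Feature Extraction 11.0.1.1. Per the file headers, the processed signal is background subtracted within each array, and it is not normalized between arrays. The deposited files also hold, as other values, flags of 0 or 1 for spots that are well above background, saturated or not uniform. The authors' normalized values are log2 values, 1 per probe name, and their sorted columns were nearly equal across the 9 arrays, as quantile normalization gives. They correlated with log2 of the scanner signal at 0.997 to 0.999 across probes and were used as an alternative. The slide and scan day of each array were read from the scan records in the file headers.

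The array has 43217 spots, of which 41800 are not control spots and hold 38804 probes. Flagged spots were left out, and spots of the same probe were averaged on the log2 scale, which concerned 184 probes. Each array's 75th percentile of log2 signal was subtracted. Probes were kept where the signal was well above background on all 3 arrays of at least 1 group, which removed 939 probes, and 222 more had no unflagged spot on some array. The remaining 37643 probes (97.0%) were tested, and 36450 of all probes were well above background on all 9 arrays. No spot was saturated. An array reading gives no count, so the number of arrays, 3 per group, limits the precision.

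Probes were named by matching accessions to a RefSeq gene table. Of the 50 catalogue probes, 30 matched, 29 of them to protein-coding genes and 1 to a placeholder symbol, and each gene has a single named probe. The other 37613 tested probes carry transcript or custom names only, so they were counted and not assigned to genes. Whether some of them measure the same genes, or members of the gene lists, is not known. No genome positions are given, because the array header names an older genome build than the gene table uses. Of 39 gene lists with 850 entries for lung, smoke and particle responses and cell types, 0 had 5 members among the named probes. Ldha was the only member named, so no list was tested.

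Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in a single fit of the 9 arrays with a mean per group, for CS against control, PM2.5 against control, CS against PM2.5 and the mean of both exposures against control, with a moderated F test over the groups. A probe passed at an adjusted p (Benjamini-Hochberg over the probes tested) below 0.05. The genes named are the 12 rising and the 12 falling genes with the largest log2 change among those that passed and whose arrays did not overlap between the groups, or all that passed where fewer did. Where fewer than 5 passed in a direction, the 5 with the smallest p in that direction are named, and those that did not pass are given as such. Placeholder symbols and probes without a gene are counted but not named, apart from 5 features chosen after their values were seen. The groups, tests, this naming rule, the gene lists and most alternatives were fixed before the data were examined. The resemblance of the CS and PM2.5 effects was set against 20 simulations with no effect and shared control arrays. The fit was tested on simulated data in which 200 of 37643 probes changed and all groups had the same spread. Log2 changes of 0.5 added to probes were recovered in 2.99% of cases in each comparison, changes of 1 in 38.8% to 43.3% and changes of 2 in 84.8% to 90.9%. Where many more probes pass, as in the comparisons against control, the adjustment is less strict, so these rates do not give the power there.

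The alternatives were quantile normalization, centring on the median of probes detected on all arrays, normexp background correction with an offset of 50 on the median spot and background signals, the authors' log2 values, no filter on dim probes or a stricter one, eBayes with a trend and robust variance, array weights, the replicate number or the slide as a block, fits of only the groups compared, a further threshold of 2-fold and leaving out each array. Others were added after the data were seen: the 3 control arrays averaged and counted as 1 sample, alone or with quantile normalization, the shared slide of CS and PM2.5 arrays alone, leaving out the exposed arrays on slides of their own, and the signal of bright-corner control spots as a covariate. The deposited files have no mean spot signal, so normexp used the median. Averaging over probes of a gene did not apply, list tests could not be run, and the replicate numbers did not pair the arrays, since in 0 of 9 pairs of arrays with the same number did the arrays correlate best with each other. The array weights did not converge, and CS 3 received a weight of 104 against 0.126 to 3.05 for the others.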

Results

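Whole-lung RNA was measured on custom 1-colour Agilent arrays, which the labels give as 1 array for each of 9 male Wistar rats. The rats formed 3 groups of 3 and were exposed for 90 days. The first group was exposed to cigarette smoke (CS) and the second to fine particulate matter (PM2.5), both as models of chronic obstructive pulmonary disease, and the control rats inhaled NS, an abbreviation that the labels do not spell out. The archiving times given are 90, 91 and 92 days for replicates 1, 2 and 3 of both exposed groups and 90 days for all control rats. Each array carried 38804 probes other than control probes, of which 37643 were tested. Of these, 50 are Agilent catalogue probes spotted 10 times each, and 30 of the 50 could be matched to a gene symbol, 29 of them to protein-coding genes. The gene results below therefore cover 29 genes, and the remaining probes are described as counts.

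Between 37259 and 38200 probes per array were well above background, and the median spot signal was 4.03 to 6.16 times the local background. The control arrays were brighter and more alike than the exposed arrays. The 75th percentile of the signal was 332 ± 6.32 (SD, n = 3) on control arrays, 201 ± 12.9 (SD, n = 3) on CS arrays and 196 ± 53.3 (SD, n = 3) on PM2.5 arrays, at the same scanner voltage. The robust spread between a pair of control arrays was 0.08 to 0.11 log2 units, against 0.19 to 0.40 between exposed arrays of the same group. The median SD of a probe within a group was 0.08 log2 units for control, 0.22 for CS and 0.27 for PM2.5. Of 184 replicated probes, 52.2% differed among the 3 control arrays by more than spot noise in an F test at the 99% level (92.9% in CS, 97.3% in PM2.5), which does not tell separate samples from repeat arrays of 1 sample. All 3 control arrays were on 1 slide scanned on the second day, and all exposed arrays were on the other 3 slides scanned on the first day, so slide, scan day and control status cannot be told apart. CS 2, CS 3, PM2.5 1 and PM2.5 2 shared a slide.

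**Figure D1:**
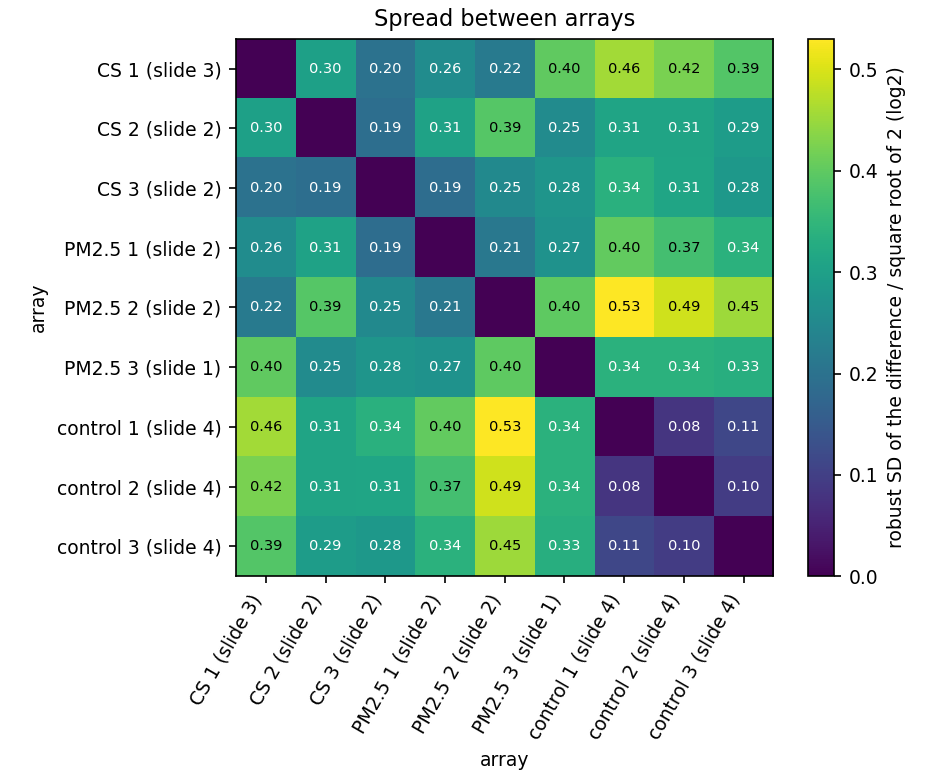
Spread between each pair of the 9 arrays, as the robust SD of the difference in log2 level divided by the square root of 2 (colour scale and printed values, log2 units), with the slide of each array on both axes. The 3 control pairs lie at 0.08 to 0.11, and pairs of a control and an exposed array lie at 0.28 to 0.53.

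The first comparison asked how lung RNA differed between CS-exposed and control rats. Of the 29 genes, 8 rose, 10 fell and 11 did not pass. The largest falls were those of Mex3c, an RNA-binding ubiquitin ligase (log2 change −0.91, SE 0.16, adjusted p = 0.00376), Pdk3, a kinase that inactivates pyruvate dehydrogenase (−0.91, SE 0.15, adjusted p = 0.00265), and Cyp2e1, a cytochrome P450 that oxidises ethanol (−0.87, SE 0.24, adjusted p = 0.0207). Cyp2e1 had a level of 2.63 ± 0.31 (SD, n = 3) on CS arrays and 3.50 ± 0.03 (SD, n = 3) on control arrays, in log2 units relative to each array's 75th percentile. The other falling genes were Pld1, which encodes phospholipase D1 (−0.72), Ldha, which encodes a lactate dehydrogenase subunit (−0.59), Ppp2r2b, a regulatory subunit of protein phosphatase 2A (−0.54), Ndfip2 (−0.52) and Ndfip1 (−0.46), adaptors of Nedd4-family ubiquitin ligases, Cdh2, which encodes N-cadherin (−0.50), and Eif4b, a translation initiation factor (−0.40). All 10 also passed after quantile scaling, with the same sign, at −0.48 (Eif4b) to −1.16 (Mex3c).

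Among the rising genes in CS lungs, the growth factor gene Fgf2 changed most in this scaling (log2 change 1.04, SE 0.25, adjusted p = 0.0111). It was followed by Lhcgr, the luteinizing hormone receptor gene (0.84), Gdnf, which encodes a neurotrophic factor (0.84), Napepld, whose enzyme releases N-acylethanolamines such as anandamide (0.68), Slc28a2, a nucleoside transporter gene (0.60), and Odf2l, a gene of the centrosome (0.60). Pop7, which encodes a subunit of ribonuclease P, rose by 0.59 (SE 0.11, adjusted p = 0.00392), and Enpp1, whose enzyme makes pyrophosphate from ATP, rose by 0.44 (SE 0.12, adjusted p = 0.0200). These rises stand against a median change of 0.44 over all probes in this scaling, which was 0.05 after quantile scaling. Fgf2, Lhcgr, Gdnf and Napepld lie at mean levels of −3.77 to −2.60, in the range of the E1A control probes, which have no rat target and were 0.70 higher on CS than on control arrays. Relative to 1001 probes of about the same level, the rising genes lay 0.08 (Napepld) to 0.58 (Odf2l) log2 units higher and the falling genes 0.55 (Eif4b) to 1.30 (Mex3c) log2 units lower. After quantile scaling, Fgf2 (0.47), Gdnf (0.32), Slc28a2 (0.52), Odf2l (0.54), Pop7 (0.51) and Enpp1 (0.39) still passed, while Lhcgr (0.24) and Napepld (0.11) did not, and Odf2l had the largest rise. After centring on the median only Fgf2 and Gdnf of the 8 passed, and with the authors' values Lhcgr, Napepld and Odf2l did not. The genes that did not pass ranged from Nat1, which encodes an arylamine N-acetyltransferase (−0.32, adjusted p = 0.0950), to P2rx2, an ATP-gated channel gene (0.50, adjusted p = 0.208, and −0.08 after quantile scaling).

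**Figure D2:**
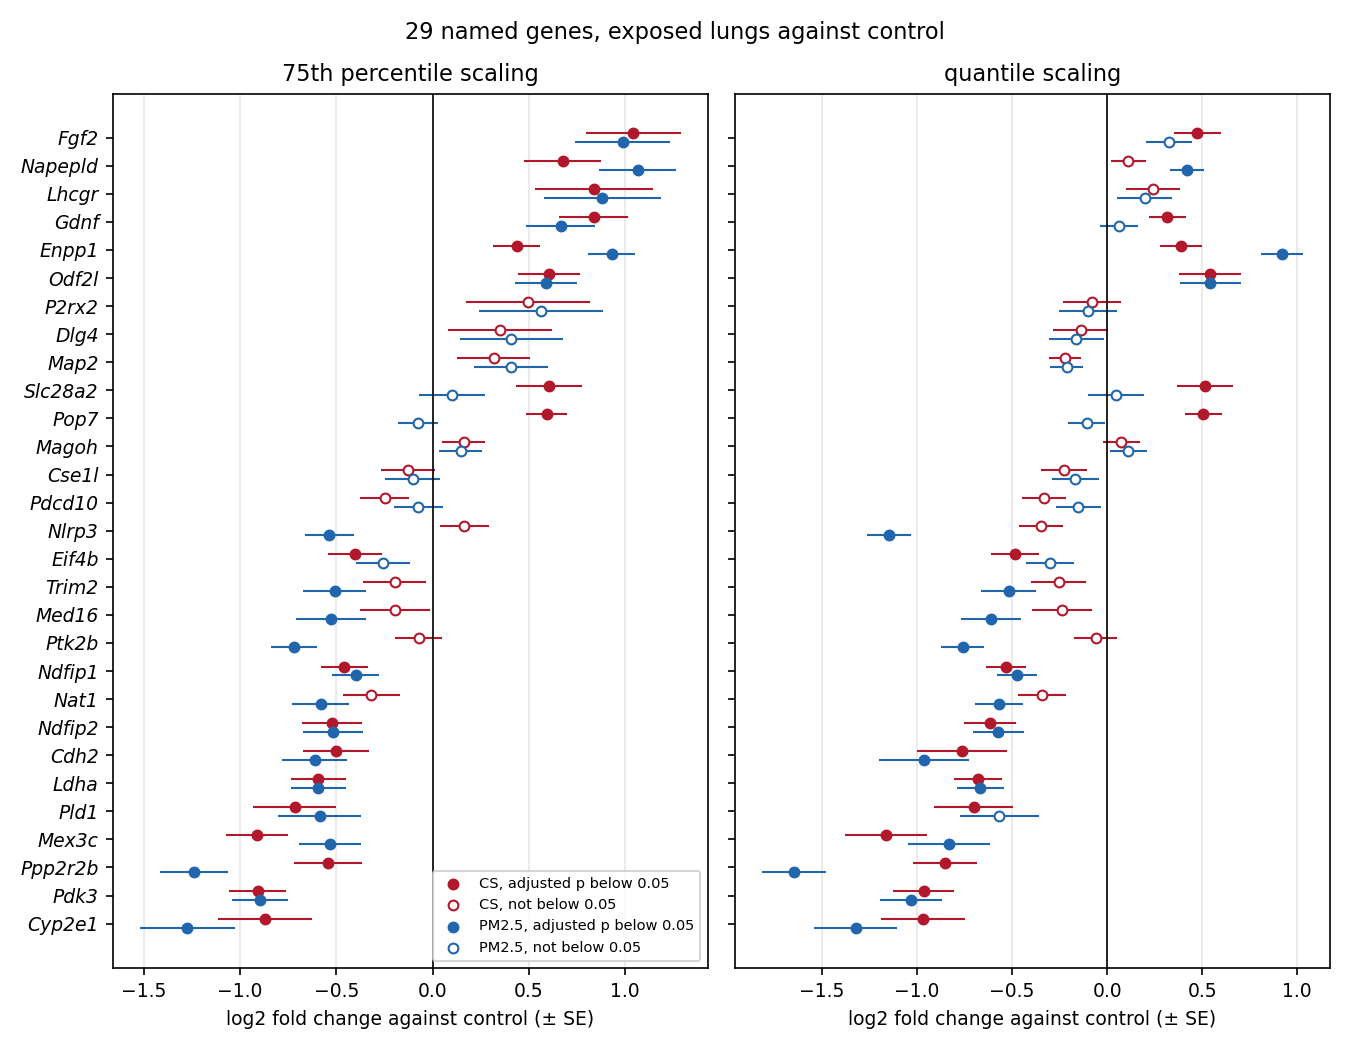
Log2 fold change against control (x axis, ± SE) of the 29 named genes (rows) in CS lungs (red) and PM2.5 lungs (blue), after 75th percentile scaling (left) and quantile scaling (right). Filled points passed an adjusted p of 0.05 and open points did not. Cyp2e1, Pdk3 and Ppp2r2b lie below 0 in both panels for both exposures, while Lhcgr passed only in the left panel.

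Over all 37643 probes, 17865 differed between CS and control, 14673 higher and 3192 lower in CS. Quantile scaling gave 9245 (4391 higher, 4854 lower), centring on the median 9094 (2879 higher, 6215 lower), normexp background correction 2387 (1224 higher, 1163 lower) and the authors' normalized values 9326 (4533 higher, 4793 lower). Of the probes called, 7485 passed with the same sign under both the 75th percentile and quantile scaling (4374 higher, 3111 lower), and 0 passed with opposite signs. The count was 2299 with slide as a random block and 165 (27 higher, 138 lower) with the 3 control arrays averaged and counted as 1 sample, and none of the 18 named genes passed in either fit (adjusted p 0.150 to 0.308 in the latter). With normexp, Pop7 and Pdk3 were the named genes that passed. Without CS 1 it was 11451, without CS 3 10475, and without control 1, 2 or 3 it was 8204, 8737 and 11002. Fgf2, Gdnf, Pop7, Mex3c and Pdk3 passed in each of the 9 fits that left out an array.

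The second comparison asked how lung RNA differed between PM2.5-exposed and control rats. Of the 29 genes, 6 rose, 14 fell and 9 did not pass. Cyp2e1 fell by 1.27 log2 units (SE 0.24, adjusted p = 0.00332) and Ppp2r2b by 1.24 (SE 0.18, adjusted p = 0.000877). Pdk3 fell by 0.90 (SE 0.15, adjusted p = 0.00163), and Ptk2b, a focal adhesion kinase relative, fell by 0.72 (SE 0.12, adjusted p = 0.00186). Nlrp3, the sensor of an inflammasome, fell by 0.54 (SE 0.13, adjusted p = 0.00815) and had a level of −3.21 ± 0.18 (SD, n = 3) on PM2.5 arrays and −2.67 ± 0.02 (SD, n = 3) on control arrays. Its mean level over all arrays, −2.80, lies in the range of the E1A control probes, which have no rat target. Also lower were Cdh2 (−0.61), Ldha (−0.59), Pld1 (−0.59), Nat1 (−0.58), Mex3c (−0.53), Med16, a subunit of the Mediator complex (−0.53), and Ndfip2 (−0.52). Trim2, a ubiquitin ligase gene (−0.51), and Ndfip1 (−0.40) fell as well but were named after their values were seen, since they lie outside the 12 largest falls. After quantile scaling, Pld1 (−0.57) no longer passed. The other 13 falling genes did, at −0.47 (Ndfip1) to −1.65 (Ppp2r2b), with Nlrp3 at −1.15, so the size of its fall depends on the scaling.

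The rising genes in PM2.5 lungs were Napepld (log2 change 1.07, SE 0.20, adjusted p = 0.00292), Fgf2 (0.99, SE 0.25), Enpp1 (0.93, SE 0.12, adjusted p = 0.000598), Lhcgr (0.88), Gdnf (0.67) and Odf2l (0.59). Enpp1 had a level of 2.65 ± 0.03 (SD, n = 3) on PM2.5 arrays and 1.72 ± 0.04 (SD, n = 3) on control arrays. The median change over all probes was 0.50 in this scaling and 0.06 after quantile scaling, and the E1A control probes, in whose range of levels Napepld, Fgf2, Lhcgr and Gdnf lie, were 0.80 higher on PM2.5 than on control arrays. Relative to 1001 probes of about the same level, Enpp1 lay 0.83 log2 units higher and Gdnf 0.02. After quantile scaling, Enpp1 (0.92), Odf2l (0.54) and Napepld (0.42) still passed, while Fgf2 (0.33), Lhcgr (0.20) and Gdnf (0.06) did not. After centring on the median Napepld, Fgf2 and Enpp1 passed, and with the authors' values Napepld and Enpp1. The genes that did not pass ranged from Eif4b (−0.26, adjusted p = 0.138) to P2rx2 (0.56, adjusted p = 0.152, and −0.10 after quantile scaling).

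Over all probes, 21416 differed between PM2.5 and control, 17712 higher and 3704 lower in PM2.5. Quantile scaling gave 11025 (5265 higher, 5760 lower), centring on the median 12524 (4770 higher, 7754 lower), normexp 3034 (1572 higher, 1462 lower) and the authors' normalized values 11229 (5529 higher, 5700 lower). Under both the 75th percentile and quantile scaling, 8805 passed with the same sign (5216 higher, 3589 lower). The count was 7777 with slide as a random block, where Napepld, Enpp1, Ppp2r2b, Pdk3 and Ptk2b were the named genes that passed. It was 1465 (906 higher, 559 lower) with the control arrays counted as 1 sample, where none of the 18 genes named by the rule passed (adjusted p 0.0628 to 0.261). With quantile scaling as well, Enpp1, Ppp2r2b and Nlrp3 passed in that fit. With normexp, Enpp1, Cyp2e1, Pdk3 and Ptk2b were the named genes that passed. Without control 1 the count was 13467, and without control 2 it was 14151. Of the 18 genes, 11 passed in each of the 9 fits that left out an array (Napepld, Fgf2, Enpp1, Gdnf, Cyp2e1, Ppp2r2b, Pdk3, Ptk2b, Ldha, Nat1 and Nlrp3), while Pld1 was lost in 8 of the fits and Med16 and Lhcgr in 6.

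**Figure D3:**
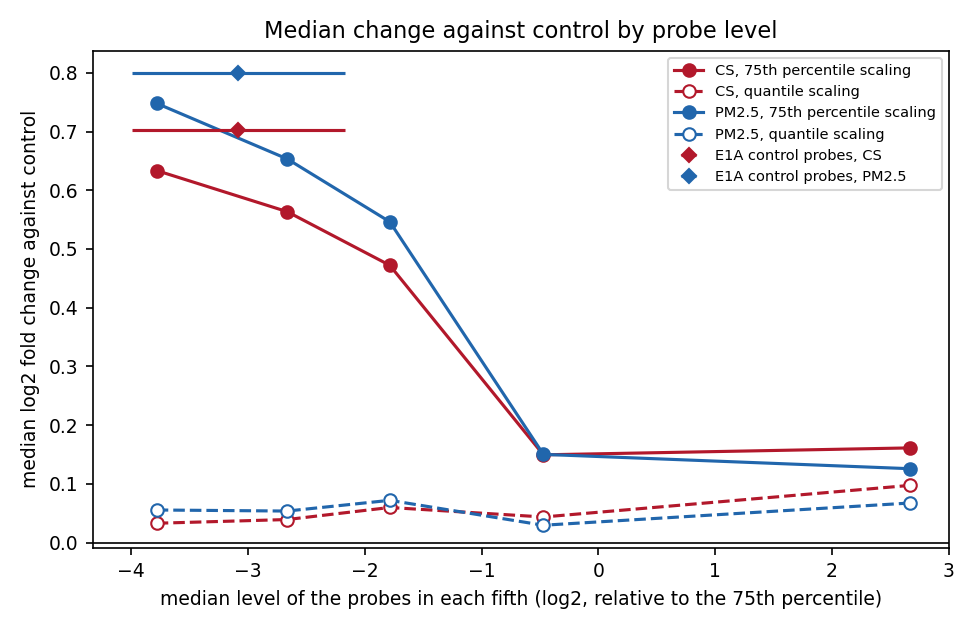
Median log2 fold change against control (y axis) for 5 groups of probes of equal size ordered by level (x axis, log2 relative to the 75th percentile), for CS (red) and PM2.5 (blue) after 75th percentile scaling (solid lines) and quantile scaling (dashed lines). Diamonds give the adenovirus E1A control probes, with their range of levels as bars. The dimmest group of probes lies at 0.63 for CS and 0.75 for PM2.5 in the first scaling and at 0.03 and 0.06 in the second.

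The effects of the exposures were then set side by side. Of the 29 genes, 6 rose in both (Enpp1, Fgf2, Odf2l, Napepld, Lhcgr and Gdnf), 9 fell in both (Mex3c, Ndfip1, Ndfip2, Ldha, Ppp2r2b, Pld1, Cdh2, Cyp2e1 and Pdk3), and 0 passed in opposite directions. After quantile scaling, 2 rose in both (Enpp1 and Odf2l) and 8 fell in both, since Pld1 no longer passed in PM2.5. The gene that rose in both was Fgf2 alone after centring on the median and Enpp1 alone with the authors' values, so none of the 6 rose in both under every scaling. Across probes, which are not independent replicates, the CS and PM2.5 log2 changes had a correlation of 0.813 and a covariance of 0.298, against 0.50 and 0.0278 in simulations with no effect and the same shared control arrays. After quantile scaling the correlation was 0.758 and the covariance 0.225, against a simulated 0.498 and 0.0193. The simulations took the control arrays as 3 separate samples and gave all groups the same spread, unlike the data. If the control arrays are 1 sample that varies like the exposed arrays, the covariance expected with no effect is 0.115, and 0.0793 after quantile scaling. The correlation expected with no effect is then also higher than the simulated one and was not computed. The gap between the measured correlations and 0.50 or 0.498 therefore cannot be read as an excess. In both comparisons 12310 probes were higher and 2383 lower, where independent lists would share 6904 and 314, a value that leaves out the shared controls. The simulations leave out the effects, called too few probes to share any, and so set no bound on the overlap. The 3 control arrays cannot be divided into parts of at least 2, so part of the excess may come from the shared controls. The overlap in the same direction was 14693 probes, and 9642 without CS 1, 8469 without CS 3, 6347 without control 1, 6873 without control 2 and 8833 without control 3. After quantile scaling 2626 probes were higher and 3630 lower in both. With the control arrays counted as 1 sample the overlap was 156, and with slide as a random block 1825.

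The mean of both exposures differed from control at 23576 probes (19841 higher, 3735 lower). Quantile scaling gave 11964 (5956 higher, 6008 lower), centring on the median 13432 (5413 higher, 8019 lower), normexp 3608 (1960 higher, 1648 lower) and the authors' normalized values 12164 (6245 higher, 5919 lower). The count was 14980 without control 1, 5413 with slide as a random block and 489 with the control arrays counted as 1 sample. A moderated F test over the 3 groups called 20935 probes, 12264 after quantile scaling, 10929 without control 1, 11305 without control 2, 13145 without control 3, 6274 with slide as a random block and 1011 with the control arrays counted as 1 sample.

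The last comparison asked where the exposures differed from each other, which is also the test of the difference between their effects against the shared controls. Its SE rests on a spread pooled over the 9 arrays. The control arrays had the lowest spread (median SD 0.08 log2 units, against 0.22 for CS and 0.27 for PM2.5), so this SE may be too small. Of the 29 genes, 3 were higher in CS than in PM2.5 lungs, 1 was lower and 25 did not pass. After quantile scaling 4 were higher, 1 was lower and 24 did not pass. Nlrp3, whose mean level lies in the range of the E1A control probes, was higher in CS by 0.70 log2 units (SE 0.13, adjusted p = 0.0124). Its log2 change against control was 0.17 in CS (adjusted p = 0.281), and −0.35 after quantile scaling, passing in neither, so the CS value has no settled sign, while its fall in PM2.5 passed in both scalings. Pop7 was higher in CS by 0.67 (SE 0.11, adjusted p = 0.00652), with 2.72 ± 0.05 (SD, n = 3) on CS, 2.05 ± 0.09 (SD, n = 3) on PM2.5 and 2.13 ± 0.05 (SD, n = 3) on control arrays. Ptk2b was higher in CS by 0.65 (SE 0.12, adjusted p = 0.0146), and Enpp1 was lower in CS (log2 difference −0.49, SE 0.12, adjusted p = 0.0471). Ppp2r2b (0.69, SE 0.18, adjusted p = 0.0536) did not pass in this scaling but passed after quantile scaling (0.79, adjusted p = 0.0170). Slc28a2 (0.50, SE 0.17, adjusted p = 0.142) did not pass, nor did Mex3c (−0.38, adjusted p = 0.254), Napepld (−0.39, adjusted p = 0.362), Pdcd10, a gene mutated in cerebral cavernous malformations (−0.18, adjusted p = 0.575), and Eif4b (−0.14, adjusted p = 0.727). Nlrp3 and Pop7 passed in each of the 9 fits that left out an array, Ptk2b in 8 of them and Enpp1 only in the fit without CS 1, with adjusted p from 0.0266 to 0.134 over the 9.

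**Figure D4:**
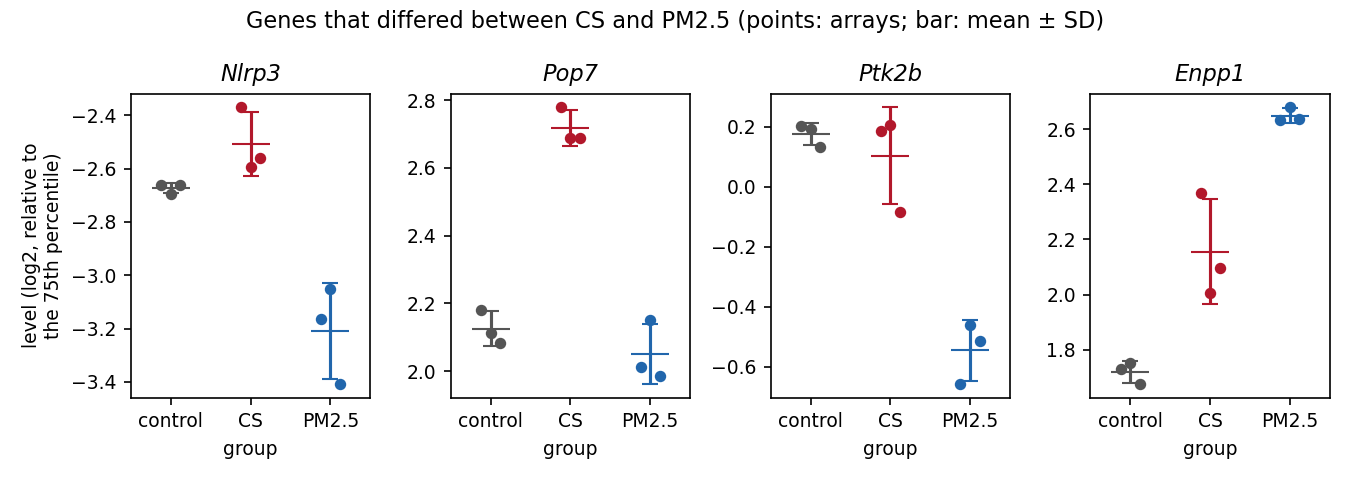
Level (y axis, log2 relative to the array's 75th percentile) of Nlrp3, Pop7, Ptk2b and Enpp1 on each array (points) with the mean ± SD (bars) in control, CS and PM2.5 lungs (x axis). Pop7 lies near 2.72 in CS and near 2.1 in the other groups, and Enpp1 is highest in PM2.5.

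On the slide that held 2 arrays of each exposure, the CS minus PM2.5 differences were 0.53 for Nlrp3, 0.60 for Pop7, 0.62 for Ptk2b and −0.61 for Enpp1. With slide as a fixed block, Nlrp3, Pop7 and Enpp1 passed and Ptk2b did not. CS 1 and PM2.5 3 each lay on a slide of their own. The fixed block therefore compares the same 2 arrays against 2, with the control arrays adding to the estimate of the spread. The replicate number goes with the archiving day in the exposed groups but not in the control group. With it as a block Nlrp3 and Pop7 passed and Ptk2b and Enpp1 did not. After centring on the median Enpp1 did not pass. With slide as a random block all 4 passed, and with the 2 arrays against 2 of that slide alone none did. Over all probes, 2226 differed between CS and PM2.5 (1196 higher, 1030 lower in CS), with 3287 after quantile scaling (1972 higher, 1315 lower), 2133 after centring on the median (1434 higher, 699 lower), 1987 with slide as a fixed block (712 higher, 1275 lower), 2377 with slide as a random block, 389 within the shared slide (145 higher, 244 lower) and 630 with the control arrays left out of the estimate of the spread or counted as 1 sample. With the control arrays counted as 1 sample none of the 4 genes passed (adjusted p 0.0815 to 0.241), although Nlrp3, Pop7 and Ptk2b passed when quantile scaling was used as well. With normexp the count was 512 (226 higher, 286 lower) and none of the 4 genes passed, with a difference of 0.21 for Nlrp3. Without CS 1 the count was 1428, and without control 1, 2 or 3 it was 1363, 1347 and 1411.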

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

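The tests of what explains a pattern were all chosen after the result was seen, and the counts over other splits of the arrays were chosen before. Of the named genes, 4 had CS effects that differed from the PM2.5 effects in the limma test of the difference itself, with log2 differences of 0.70 for Nlrp3, 0.67 for Pop7, 0.65 for Ptk2b and −0.49 for Enpp1. Beyond the named genes, and chosen after the values were seen, the placeholder gene LOC108352165 was 1.48 log2 units higher in CS than in PM2.5 (SE 0.17, adjusted p = 0.00112). It fell by 1.55 in PM2.5 against control, and in CS it had a value of −0.07 that did not pass and of −0.51 after quantile normalization, which passed. On the slide with arrays of both exposures the difference was 1.30. With normexp background correction neither the difference (0.46) nor the PM2.5 change (−0.49) passed. The mean level of LOC108352165, −2.65, lies in the range of the E1A control probes. The transcript probe XR_146859, chosen in the same way, differed by −2.19 (SE 0.15, adjusted p = 7.25e-05). It rose by 1.47 in PM2.5 and fell by 0.72 in CS against control, and the difference was −2.08 on the shared slide. The CS fall did not pass with the control arrays counted as 1 sample or with slide as a random block, while the PM2.5 rise and the difference passed in both.

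The control probes for adenovirus E1A, which measure no rat gene, were 0.75 log2 units higher on exposed than on control arrays after scaling to the 75th percentile. They stand beside the shift of dim rat probes in the same range of levels, −4.00 to −2.17, whose median was 0.63 over 12752 probes. A difference in signal scale between exposed and control arrays predicts that the 10 E1A probes move too, and their median shift was 0.754. The 75th percentile that was subtracted averaged 332 on control, 201 on CS and 196 on PM2.5 arrays. A probe with equal signal on all arrays therefore reads higher on exposed arrays after this scaling. A difference in signal scale thus stays open as the cause. More of the transcripts that dim probes measure would move rat probes beyond the E1A probes, but the rat median minus the E1A median was −0.126 (SD among E1A probes 0.124), which argues against it as the whole cause. The amount of E1A RNA on each array is not stated in the labels, and a change in single dim genes was not excluded.

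The control arrays differed far less from one another than the exposed arrays. A shared slide and scan stays open as the cause, since the most alike pair of exposed arrays on a shared slide had 1.70 times the spread of the least alike control pair, but only 2 such pairs exist, both on 1 slide, and exposed arrays of a group were at 0.19 to 0.21 on 1 slide and 0.20 to 0.40 across slides. A single RNA sample on the 3 control arrays cannot be told apart from animals that vary little. The probes most variable in one exposed group had 1.32 times the SD of other probes in the control arrays, against 2.51 times in the other exposed group, a value between those that each explanation predicts. A rise in the spread between animals with exposure stays open as well, since 0 slides hold control and exposed arrays.

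The CS and PM2.5 effects resembled each other, with a correlation of 0.813 across probes. Chance values of the shared control arrays stay open as a cause. The covariance of the effects was 10.7 times that simulated with no effect. Those simulations gave all groups the same spread and took the control arrays as 3 separate samples. The covariance was 2.59 times that expected if the control arrays are 1 sample that varies like the exposed arrays. That expected value is an average over probes and gives no range for probes that move together, so it cannot decide the question. Array brightness stays open, because only PM2.5 3 differed clearly in brightness from the other PM2.5 arrays, and its slope of 0.880 relative to theirs, where brightness predicted 0.368, rests on that array and on the shared control arrays. The slide and scan day that separate control from exposed arrays cannot be told apart from an effect shared by both exposures, because 0 slides hold both. A shared effect of the exposures therefore stays open as an untested explanation.

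Other splits of the arrays were counted for each comparison. For CS against control and PM2.5 against control the 10 splits are too few for a share under 0.05, with 17865 and 21416 probes for the real splits, each the only 1 of the 10 to call as many, and 0 for the highest other split. For CS against PM2.5 the 10 splits are also too few, and 2 of them called as many, with 2226 probes for the real split and 6142 for the highest other. That other split sets CS 1, PM2.5 1 and PM2.5 2 against CS 2, CS 3 and PM2.5 3. It points to a structure among the arrays that does not follow the slide, and whether it lies in the samples or in the arrays is not known. Among measures looked at after the split was seen, the bright-corner control signal divides the arrays in the same way, at 287 to 358 against 753 to 1221, and so does the median level of the control spots, at −2.51 to −2.16 against −3.03 to −2.61. The control arrays lie beyond all exposed arrays on both measures, at 1632 to 1892 and −3.45 to −3.24. Neither measure can therefore be told apart from control status in the comparisons against control. With the bright-corner signal as a covariate, 3929 probes differed between CS and PM2.5, and with slide as a fixed block 1987. For both exposures against control, chance can be excluded only if the 3 control arrays are separate samples, with 2 of 100 splits calling as many as the real 23576 and 24767 for the highest other, which keeps the control arrays together. The same condition holds for the F test over the 3 groups, with 1 of 100 splits, the real one at 20935, and 18516 for the highest other. Whether the control arrays are separate samples stays open, the counts with them as 1 sample were 489 and 1011, and neither count separates the groups from the slides.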

How the results depend on the processing

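The fits with control arrays counted as 1 sample, without the exposed arrays on slides of their own, within the shared slide and with the bright-corner signal were chosen after the data were seen. Signal over background limits the dim probes, since the median signal was 4.03 to 6.16 times the local background, and the exposed and control arrays share no slide. Over the 46 gene results chosen by the naming rule, 794 values under an alternative kept their direction and side of the threshold, 280 kept the direction and no longer passed, 14 newly passed and 0 reversed. Among all 29 genes, quantile normalization turned the sign of 4 changes in CS, 3 in PM2.5 and 7 differences between them, none of which passed under either scaling, with Nlrp3 in CS (0.17 to −0.35) and P2rx2 in CS (0.50 to −0.08) and PM2.5 (0.56 to −0.10) among them. The correlation of effects was 0.754 to 0.821 over the fits that left out an array. Its spread, a jackknife SD of 0.0603, was computed from those same fits, so they could not fall far beyond it. Centring on the median, the replicate block, the trend and robust variance, and the control arrays counted as 1 sample left it at 0.813 by construction. Among the alternatives that could move it were normexp at 0.777, quantile normalization at 0.758 and slide as a random block at 0.810, all within that spread. The counts below are given in the order CS against control, PM2.5 against control, CS against PM2.5, both exposures against control, any difference among the groups, and overlap, leaving out comparisons whose count stayed within 1.5 times. The cause was not tested for any of them, except that fewer samples enter the fits with control arrays counted as 1 sample, of only the groups compared and within the shared slide. For CS against PM2.5 these fits also take the control arrays, which had the lowest spread, out of the estimate of the spread. Normexp gave 2387, 3034, 512, 3608, 3406 and 1442. Quantile normalization gave 9245, 11025, 11964 for both exposures, 12264 and 6256. Centring on the median gave 9094, 12524, 13432 for both exposures, 12347 and 6880. The authors' values gave 9326, 11229, 12164 for both exposures, 12393 and 6320. Array weights gave 33636 for CS, 16324 for CS against PM2.5, 35581 for any difference and 27492 for the overlap. Slide as a random block gave 2299, 7777, 5413 for both exposures, 6274 and 1825. The control arrays counted as 1 sample gave 165, 1465, 630, 489, 1011 and 156, and with quantile normalization 505, 2293, 1313, 1449, 2439 and 446. A further threshold of 2-fold gave 2549, 4117, 654 and 2806, and with an unadjusted p 2621, 4163, 768 and 2823. For CS against PM2.5, the replicate block gave 1240, only the groups compared 630, the shared slide alone 389 and the bright-corner covariate 3929. With the replicate block 32 of the 40 gene results that had passed still did, and the other counts were 12712, 17741, 20520 and 15502, with an overlap of 10210. Leaving out each array gave 8204 to 22027 for CS, 13467 to 24988 for PM2.5, 1347 to 2584 for CS against PM2.5, 14980 to 26575 for both exposures, 10929 to 25679 for any difference and 6347 to 18611 for the overlap. The lowest were without control 1, except 1347 without control 2. Averaging over probes of a gene and the list tests were not run, since each gene had 1 named probe and no list had enough members among the named probes.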

Other observations

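The tests below were chosen after the values were seen. Probes named uc. formed the one family of unnamed probes looked at closely, and 850 of them were tested. With the same sign under the 75th percentile and quantile scaling, 82 differed between CS and control (40 higher, 42 lower), 102 between PM2.5 and control (56 higher, 46 lower) and 23 between CS and PM2.5 (16 higher, 7 lower). Over all 37643 probes these counts were 7485, 8805 and 2092, a higher rate than among uc. probes. The uc. probes are dim, with median levels of −4.05 on control, −3.46 on CS and −3.35 on PM2.5 arrays. The rates are therefore not compared at equal level. Of the dimmest 7529 probes (median level −3.78), at most 227 higher and 77 lower in CS passed under both scalings. For PM2.5 the bounds were 365 and 103, and for CS against PM2.5 they were 41 and 50. These are lower rates than among uc. probes, but the probes were not matched by level. Probes whose names differ only in a plus or minus sign were measured for 383 elements, and across them the changes of the paired probes had a correlation of 0.0839 in CS and 0.160 in PM2.5 after quantile scaling. The names are not defined in the files, so no strand or gene is assigned to them.

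Of the uc. probes that passed under both scalings in CS, uc.247+ rose most and uc.47- fell most. The probe uc.247+ rose by 4.54 log2 units in CS (SE 0.80, adjusted p = 0.00363) and by 2.87 in PM2.5 (SE 0.80, adjusted p = 0.0155). With normexp the CS change was 1.95, and the probe's control levels of −4.92 to −4.54 lie below the dimmest E1A control probe (−4.00), so the size of the change is not settled. The PM2.5 arrays were at −3.92, −0.18 and −1.35. It passed in neither with the control arrays counted as 1 sample or with slide as a random block, and its PM2.5 change no longer passed after quantile normalization (2.30) or normexp (1.13). The probe uc.47- fell by 3.85 log2 units in CS (SE 0.24, adjusted p = 4.57e-05) and by 3.50 in PM2.5 (SE 0.24, adjusted p = 2.98e-05), and it passed in both with the control arrays counted as 1 sample (adjusted p = 0.0101 and 0.00672). With normexp its changes were −2.61 and −2.44 and passed. The transcript probe ENSRNOT00000020272.7 fell by 1.77 in CS (SE 0.15, adjusted p = 0.000174) and by 1.69 in PM2.5 (SE 0.15, adjusted p = 8.64e-05), and it passed in that fit too (adjusted p = 0.0426 and 0.0226) and with normexp (−1.56 and −1.51).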
